A study of Arvicanthis niloticus with 59 samples.

How the data were processed

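The data were RNA-seq gene tables of the Nile grass rat (Arvicanthis niloticus), a day-active rodent. They covered 59 libraries from 48 sampled sites in 22 organs of 4 animals, which the labels name T3F, T173F, T426 and T424. Per the labels' protocols, the libraries were made from polyadenylated RNA of healthy, untreated tissue with an Illumina TruSeq kit and sequenced in paired ends.

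The authors deposited 2 tables of the whole series, with genes in lines and libraries in columns. One holds expected counts, the estimated counts that RSEM assigns to each gene and that need not be whole, as deposited by the authors; 54.76% of these values were whole numbers. The other, also as deposited, holds TPM, a length-scaled transcript abundance, for the same genes, and every column of it summed to 1000000. The submitters' processing notes name RSEM, with no version, and Bowtie 0.12.8. The genome build or transcript assembly and its annotation are not given in the sources used here. Each column name matched the title of a single library, and 0 columns of values were left without one.

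The tables list 18970 genes by symbol, and 18950 of them had a count in some library. Of the symbols, 14498 (76.43%) matched the RefSeq gene table of this species when case was ignored; symbols are printed as the authors' tables give them, in mouse form. RSEM shares a read between similar transcripts, so levels of genes with a near-identical copy are uncertain. Among the genes named here this concerns the defensins, amylases, trypsins, the Reg3 genes, the Y-linked genes with an X-linked copy and mitochondrial genes with nuclear copies. Total expected counts per library ran from 678819 to 41309569, with a median of 16406604. At 3 counts, the smallest total counted as more than nothing here, the depth of a library sets the lowest level that can be seen; intervals from counts would cover counting error only and are not given for whole organs.

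Libraries were grouped by the site, tissue and animal in their titles. For the tests, expected counts were rounded to whole numbers and analysed with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the package's own filter on low counts and Benjamini-Hochberg adjustment. A gene was called at an adjusted p below 0.05 with an absolute log2 fold change of at least 1. The left and right retina of T3F were summed, so that each animal entered a site once: they differed beyond counting noise (chi-square per gene 13.41 over 15010 genes), so they were separate libraries, but they came from a single animal. Genes differing among the 10 sites with libraries of 2 animals were tested jointly over 20 libraries. A gene was site-enriched where the site exceeded each of the other 9 sites in a test of its own. Beside hippocampus, duodenum and renal pelvis these sites include no other part of brain, intestine or kidney. Enrichment there is thus against other organs and not against neighbouring parts. Single genes were also tested against the mean of the other 9 sites, there with no minimum fold. P-values of these sites rest on 2 animals each, which are not the same pair of animals at every site. Comparisons between sites with 1 library (kidney, stomach, fat, heart, cerebellum) used a model of all libraries, in which a lone library is assumed to vary like the replicated sites; its dispersion trend came from the replicated sites. Small and large intestine were compared over 7 libraries, and T426 with T3F over the 7 sites that both supplied, with site as a block.

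Organ-enriched genes were defined by size alone, on the deposited TPM: a mean of at least 1 TPM in an organ and at least 4 times the mean of every other organ. The nearest library was the one with the highest Spearman correlation of log2(TPM + 1) among libraries of other animals. A total of 68 gene lists, 45 for cell types, 22 for pathways and 1 for sex-linked genes, were written from general knowledge. Pathway lists with 5 or more tested genes were tested at each replicated site with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and an inter-gene correlation of 0.01; fry and an estimated correlation were run beside it. List means by library are means of log2(TPM + 1).

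The groups, tests, thresholds, gene lists and most of the other settings tried were fixed before the data were examined. So was the rule for named genes: up to 3 site-enriched genes per site, up to 5 genes per direction of a contrast with a mean of at least 10 TPM, ordered by fold change, the organ-enriched gene with the highest ratio to the next organ, and 2 to 4 members of most lists described, those with the smallest adjusted p or, with no test, the highest TPM. In the islet, photoreceptor, brown fat, clock and sex-linked lists any member could be named. Which lists are described at which site was chosen after the tests, and so were the most abundant organ-enriched genes and Alb, Ivl and Myl7. Some genes that the rule names are not reported here. The other settings were DESeq2 size factors in edgeR, no filter, DESeq2 1.42.0 itself, limma with trend on log2(TPM + 1), the animal as a replicate block, the left retina alone, other thresholds, and leaving out each library. The labels tie same-named samples to 1 animal, so the animal numbers pair the samples. Deviations of T426 from the site mean correlated between sites with a median of 0.126 over 21 pairs of its 7 sites (0.0189 to 0.808). Scaling by DESeq2 size factors in place of TMM shifted no contrast by more than 0.1 on the log2 scale; the widest shift was 0.082, in the comparison of animals.

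A pair of reduced data sets was chosen after seeing the data, because some libraries held genes of another organ. The reduced set left out the libraries labelled liver T3F, lung T3F and pancreas T173F. The strict set also left out the T426 libraries of retina, hippocampus, femur, sciatic nerve and renal pelvis. Where a library was left out for its genes of another organ, lower counts of those genes follow from that choice. They are no test of where the genes came from. Liver and pancreas thus have 1 library each in both sets, and femur, hippocampus, retina, renal pelvis and sciatic nerve in the strict set. Counts of these sites there rest on 1 animal, assumed to vary like the remaining pairs. Neither set is free of genes of another organ. In the strict set the mean log2(TPM + 1) of the acinar list was 8.35 in muscle, 8.28 in colon and 7.14 in sciatic nerve of T3F. That of the hepatocyte list was 7.31 in cornea T3F. Femur T3F, the bone library left there, had the trachea-enriched genes Dcpp1 and Scgb1a1 at 6598 and 3689 TPM. A dispersion trend from all libraries was likewise added later.

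Each kind of edgeR comparison was run on simulated counts drawn from the real means and library sizes; DESeq2, limma, fry and the other settings were not. In the 10 sites, 0 of 67 genes changed 4-fold in a site were found to differ, 30 of 67 changed 16-fold and 60 of 66 changed 64-fold, with 3 false calls among 17049 genes. The site-enriched rule found 0 of 67, 2 of 67 and 21 of 66 at these sizes. The test against the mean of the other sites found 28 of 67, 59 of 67 and 63 of 66, with 27 false calls, more than 1 in 20 of its calls. Between lone libraries (kidney, stomach, fat, heart) 0 of 67, 0 of 67 and 0 of 66 were called in each, and cerebellum against the other brain sites gave 2 of 67, 42 of 67 and 61 of 66, with 15 false calls among 18096 genes, again more than 1 in 20 of its calls. In the intestine 67.2%, 95.5% and 98.5% were called, with 12 false calls among 14400 genes, also more than 1 in 20 of the calls, and in the comparison of animals 43.3%, 89.4% and 93.8%, with 4 among 15096. Of 50 simulated lists camera called the 1 changed list and 0 others. The organ rule found 1 of 67, 66 of 67 and 66 of 66. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, using pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.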

Results

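RNA was measured in 59 libraries of the Nile grass rat, a day-active rodent, from 22 organs. Animal T3F gave 38 libraries of 37 sites, with total expected counts of 12693819 to 41309569 (median 18420427). Animal T173F gave 12 libraries (1573234 to 23901468, median 8011760), T426 gave 8 (1691561 to 3827321, median 2512942), and T424 gave a testis library of 678819. Between 6703 and 15687 genes reached 1 TPM per library, with a median of 13904. Libraries of 2 animals were present for 10 sites, and 9 organs had 1 library, so values of sites with 1 library have no replicate. The series title names a comparative RNA-seq pipeline, and the labels allow organs, sites and animals to be compared.

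Genes enriched in an organ were described first, over all 59 libraries. The atrial peptide gene Nppa reached a mean of 99890 TPM in heart against 228.9 in the next organ, the gastric protease precursor Pgc 165300 in stomach against 78.08, and the recombinase subunit Rag1 of developing lymphocytes 5164 in thymus against 114.8. The urothelial plaque gene Upk1a reached 5448 TPM in bladder against 17.88. Of 18970 genes, 3005 were organ-enriched. Testis held 752 of them (25.02%), pancreas 421 (14.01%), brain 248, eye 227, thymus 194 and intestine 186. The labels put a midbrain library under eye and adrenal libraries under kidney and adipose; grouped by site name, testis held 643, brain 363 and eye 250 of 2973. All 14 listed T cell and thymocyte genes were enriched in thymus, all 22 phototransduction genes and all 12 rod genes in eye, 11 of 13 cone genes in eye, and 10 of 15 cardiomyocyte genes in heart. The gene with the highest ratio to the next organ was Gdf7, a growth factor of the BMP family, in uterus (205.8 TPM against 7.037), Dynap in the esophagus (55.33 against 0.5415) and Hhla1 in muscle (97.52 ± 16.65 TPM, SD, n = 2, against 2.323), and the histone gene Hist1h2ba reached 780.5 TPM in testis and was listed at 0 elsewhere. This was a description by size with no test.

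A few organs held genes of another organ. The library labelled lung T3F had the liver genes Fgg (fibrinogen) at 6611 TPM and F9 (a clotting factor) at 3973 TPM, and its most abundant gene was Alb, serum albumin, at 71560 TPM. In the library labelled liver T3F the surfactant genes Sftpc and Sftpb reached 23830 and 3284 TPM, and both were listed at 0 in liver T426; 6 of 11 alveolar epithelium genes were thus enriched under the label liver. The pancreas library of T173F had 1573234 counts and 6703 genes at 1 TPM, and its most abundant gene was Gm42421 at 38710 TPM, which was listed at 0 in every other organ. Without the libraries labelled liver T3F, lung T3F and pancreas T173F (the reduced set), 2988 genes were organ-enriched, and liver held 249 in place of 44 and pancreas 39 in place of 421; lung had no library left in this set. Without the T426 libraries of retina, hippocampus, femur, sciatic nerve and renal pelvis as well (the strict set), the total was 3120, with 251 in liver and 42 in pancreas. Testis held 954 in that set, in place of 752. Of the pancreas genes, 28 were shared between the full and the strict set, and of the liver genes 3.

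**Figure D1:**
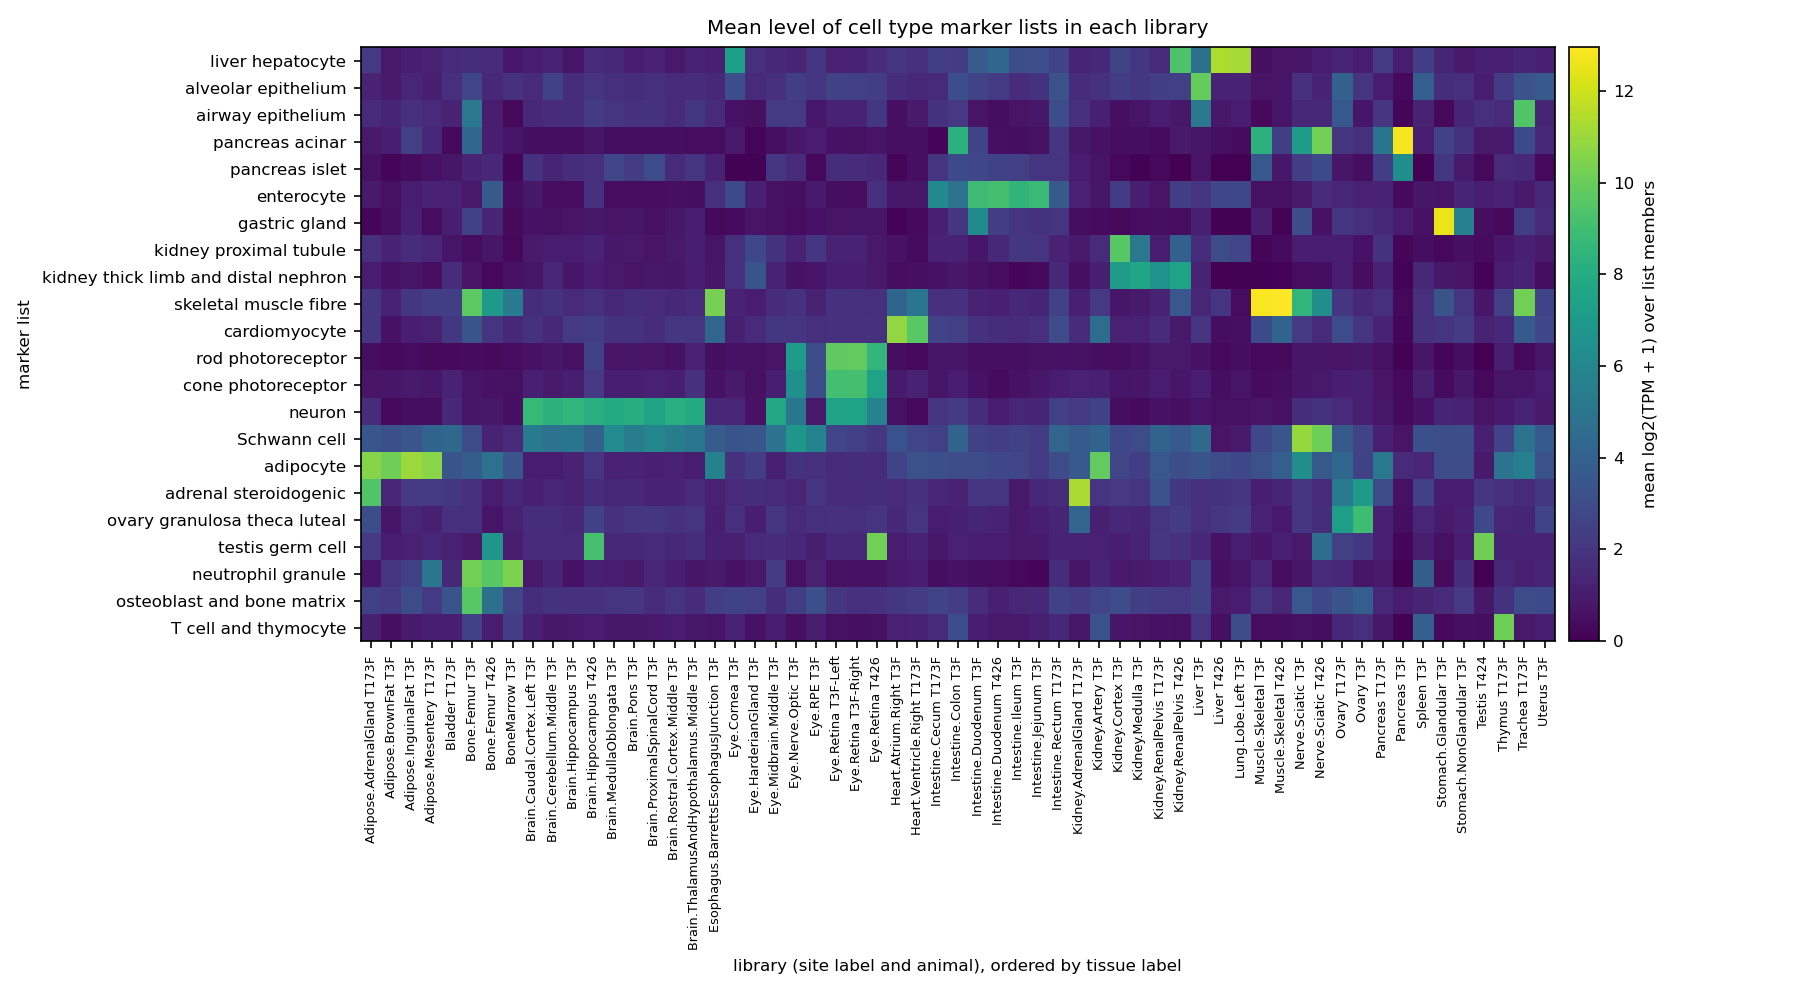
Mean log2(TPM + 1) of 22 cell type lists (vertical axis) in each of the 59 libraries (horizontal axis), drawn as color from low to high. The alveolar list stands at 9.88 in the library labelled liver T3F, the hepatocyte list at 11.21 in the library labelled lung T3F and the germ cell list at 10.22 in retina T426.

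The 10 sites with libraries of 2 animals were then compared. Of 17564 genes tested, 7271 (41.4%) differed among the sites by edgeR. Without pancreas T3F the number was 12521, the one left-out library of 20 to move it over 1.5 times. For 21 libraries of these sites the nearest library of another animal came from their own site in 8 cases, from their own organ in 11 and from another organ in 10. The rank correlation with the own site had a median of 0.81 (0.371 to 0.932). It was 0.932 for duodenum, 0.931 for muscle, 0.914 for sciatic nerve, 0.886 for renal pelvis and 0.851 for ovary. For hippocampus it was 0.81, for femur 0.7, for retina 0.664 to 0.667 and for pancreas 0.371. Retina T426 lay nearest to testis T424 (0.711). Liver T426 lay nearest to the library labelled lung T3F (0.913), and its correlation with the library labelled liver T3F was 0.709. These correlations are across genes, which are not independent replicates. Site-enriched genes, those higher than at each of the other 9 sites, numbered 0 to 43 per site, and in most sites the loss of nearly any library moved that number over 1.5 times. Over 22 pathway lists and 10 sites, 119 of 220 camera tests passed, 6 of them with an estimated correlation and 38 by fry. With the animal as a block, 18 of the 220 calls changed, none of them in a list and site described here.

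**Figure D2:**
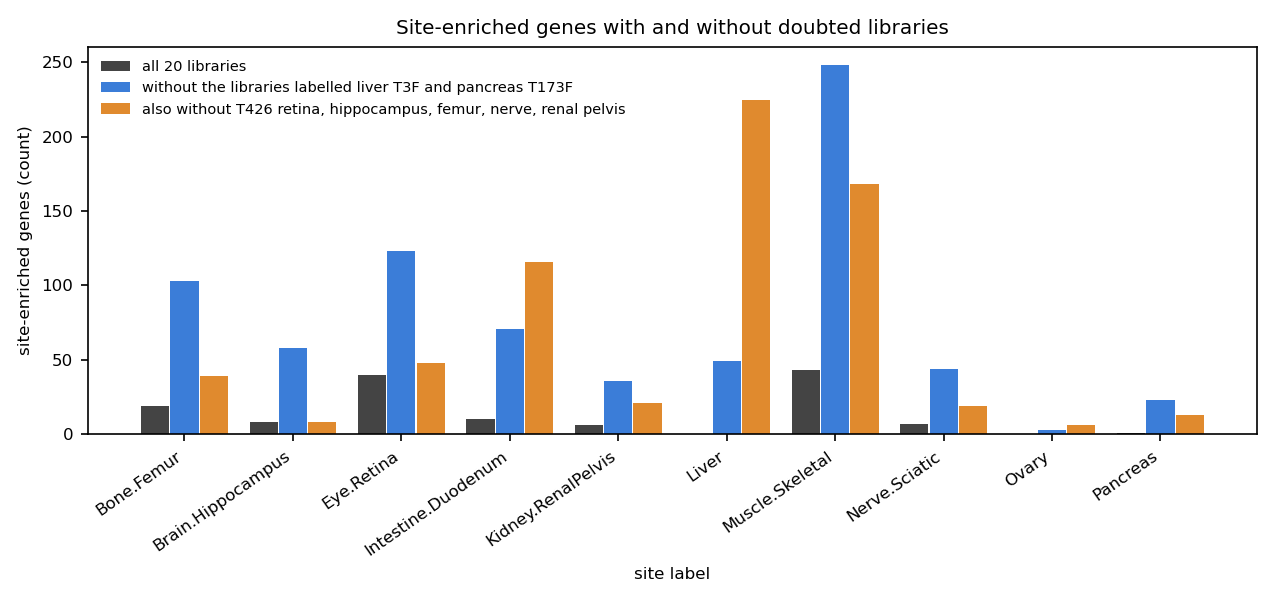
Number of site-enriched genes (vertical axis) at each of the 10 sites with 2 animals (horizontal axis), with bars for all libraries, for the reduced set and for the strict set. Skeletal muscle has 43, 248 and 168 genes, liver 0, 49 and 225. Liver and pancreas have 1 library each in the reduced and the strict set, and femur, hippocampus, retina, renal pelvis and sciatic nerve in the strict set, so these bars rest on 1 animal.

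In the femur, genes of blood-forming marrow and of bone were high in both animals. Neutrophil granule genes led: Ngp reached 4499 ± 2133 TPM (SD, n = 2), Camp, a cathelicidin, 4890 ± 718, and Ctsg, cathepsin G, 752.6 ± 325, against 3.37, 8.69 and 0.702 TPM at the next site. Of 11 such genes 11 were higher than the mean of the other sites (11 adjusted over the list alone) and 6 were site-enriched. Klf1, a transcription factor of red cell precursors, lay 8.90 ± 0.56 log2 units (SE) above the mean of the other sites (adjusted p = 7.29e-07), and 8 of 9 erythroid genes were higher (9 adjusted over the list alone). Among bone matrix genes 10 of 11 were higher (10 adjusted over the list alone), with the osteocyte genes Mepe at 13560 TPM in T3F and 1377 in T426 and Sost at 1914 and 102.2. Of 8 osteoclast genes 5 were higher (6 adjusted over the list alone), such as Acp5 at 5.11 ± 0.64. Sarcomere genes were higher too, in 25 of 27 (25 adjusted over the list alone; camera adjusted p = 1.26e-25, adjusted p = 0.0354 with an estimated correlation); Myoz1 stood at 100.6 TPM in femur against 2418 in muscle. The cell cycle list passed (adjusted p = 3.19e-17, adjusted p = 0.15 with an estimated correlation). Site-enriched genes numbered 19, with 126 by DESeq2, 63 by limma, 103 in the reduced and 39 in the strict set and 0 to 75 with 1 library left out, and the calls of Ngp, Ctsg and Defa37 (4583 ± 529 TPM) ended without 10, 17 and 18 of the 20 libraries. Those of Ctsg and Defa37 also ended by DESeq2 (11.03 and 11.60 above the nearest site), in the strict set (Defa37 at 11.76) and with an animal block (10.91 and 12.24), and that of Defa37 in the reduced set (13.31). Germ cell genes were higher in 6 of 13 (9 adjusted over the list alone), 3 in the reduced set and 0 of 6 in the strict set; their mean was 6.76 log2(TPM + 1) in T426, against a median of 1.27 over all libraries.

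In the hippocampus, neuronal and glial genes stood far above the mean of the other sites. Snap25, part of the vesicle fusion machinery, reached 579.8 ± 82.8 TPM (SD, n = 2) and lay 9.47 ± 0.59 log2 units above the mean of the other sites (adjusted p = 2.18e-07), and the glutamate receptor Gria1 lay 9.03 ± 0.56 above. All 15 neuron genes were higher (15 adjusted over the list alone), 10 of 12 projection neuron genes (11), including Camk2a at 9.09 ± 0.73, 10 of 10 oligodendrocyte genes (10), including Ermn at 7.99 ± 0.74, and 7 of 9 astrocyte genes (8), including Gfap at 7.32 ± 0.52. Of 27 synaptic genes 26 were higher (27 adjusted over the list alone; camera adjusted p = 1.76e-24, adjusted p = 0.0125 with an estimated correlation). The T426 library also held sperm cell genes: Akap4, of the sperm tail, had 1346 TPM and Prm2, a protamine, 1955 TPM, and both were listed at 0 in T3F. Of 13 germ cell genes 7 were higher (12 adjusted over the list alone), 2 in the reduced set and 0 of 6 in the strict set; without T426 Akap4 and Prm2 stood at −4.36 and −4.92, and their calls ended without 13 and 15 of the 20 libraries. Site-enriched genes numbered 8, with 66 by DESeq2, 184 by limma, 13 under an animal block, 58 in the reduced and 8 in the strict set and 0 to 24 with 1 library left out. The calls of Neurod6 (1411 ± 338 TPM), Olig1 (400.5 ± 124.5) and Ntsr2 (267.7 ± 10.66) ended without 14, 18 and 11 of the 20 libraries. Those of Akap4 and Prm2 ended in the reduced set (9.58 and 9.93 above the mean of the other sites), by limma (3.87 and 3.92) and with an animal block (5.49 and 7.14). Those of Neurod6 and Olig1 ended by DESeq2 (9.03 and 8.24 above the nearest site) and in the strict set (9.14 and 8.01).

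The retina was marked by photoreceptor genes. The rod phosphodiesterase subunit gene Pde6a reached 234.3 ± 155.5 TPM (SD, n = 2, the sides of T3F averaged) against 0.726 at the next site and lay 11.54 ± 0.49 log2 units above the mean of the other sites (adjusted p = 4.82e-08). Among cone genes, cone arrestin Arr3 lay 14.24 ± 0.67 above, with 2376 TPM in T3F and 981.4 in T426, and the middle-wavelength opsin Opn1mw had 2737 and 802.8 TPM. All 12 rod genes (12 adjusted over the list alone), 13 of 13 cone genes (13) and 22 of 22 phototransduction genes (22) were higher, and 3, 5 and 13 of them were site-enriched; the last list passed camera (adjusted p = 1.04e-34, adjusted p = 0.0078 with an estimated correlation). Synaptic genes were higher in 24 of 27 (25 adjusted over the list alone; adjusted p = 6.84e-16, adjusted p = 0.0354 with an estimated correlation), and ribosomal protein genes were lower by camera (adjusted p = 1.59e-14, adjusted p = 0.414 with an estimated correlation). Germ cell genes were higher in 12 of 13 (12 adjusted over the list alone) and in 0 of 6 in the strict set: Odf2 had 117.2 TPM in T3F and 1341 in T426, Spata18 0.650 and 149.8, and without T426 Spata18 stood at −0.62 and the call of Odf2 ended. Site-enriched genes numbered 40, with 116 by DESeq2, 197 by limma, 123 in the reduced and 48 in the strict set and 0 to 84 with 1 library left out. The calls of Csn3 (1392 ± 60.9 TPM), Pde6h and Cplx4 ended without 4, 9 and 5 of the 20 libraries, those of Spata18 and Odf2 in the strict set (Odf2 at 1.12), and that of Spata18 by limma (2.61).

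The duodenum was marked by the absorptive epithelium. Villin (Vil1), of the brush border, reached 557.6 ± 90.8 TPM (SD, n = 2) against 6.68 at the next site and lay 7.93 ± 0.45 log2 units above the mean of the other sites (adjusted p = 1.36e-07). The glucose transporter Slc5a1 lay 11.74 ± 0.89 and the alkaline phosphatase Alpi 12.87 ± 1.05 above. Of 17 enterocyte genes 15 were higher (15 adjusted over the list alone), and of 10 goblet and Paneth genes 9 (9), including the mucin Muc2 at 8.54 ± 0.98. The named site-enriched genes were Cdhr2, a brush border cadherin, at 1630 ± 341 TPM, Ptprh at 179.8 ± 20.6 and Ms4a10 at 182.1 ± 66.6, whose calls ended without 8, 12 and 12 of the 20 libraries. Site-enriched genes numbered 10, with 95 by DESeq2, 175 by limma, 20 under an animal block, 71 in the reduced and 116 in the strict set and 0 to 66 with 1 library left out.

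The renal pelvis showed genes of the kidney medulla and of the urothelium. The urea transporter Slc14a2 reached 413.9 ± 141 TPM (SD, n = 2) against 0.355 at the next site, and the cadherin Cdh16 538.6 ± 132.7. Of 11 thick limb and distal nephron genes 10 were higher (10 adjusted over the list alone), with Slc12a1, the salt transporter of the thick limb, at 104.8 TPM in T173F and 1793 in T426. Of 9 urothelium genes 5 were higher (7 adjusted over the list alone), among them Psca at 7.81 ± 0.44 log2 units (adjusted p = 2.41e-07). Liver genes were present in T426: the fibrinogen gene Fga had 844.8 TPM there and 0.288 in T173F, and Ahsg 1684 and 0.827. Of 16 hepatocyte genes 12 were higher (14 adjusted over the list alone), and 1 in the strict set; 3 of 12 proximal tubule genes were higher (6 adjusted over the list alone), and 0 in the strict set. Without T426, Fga, Ahsg, Pck1 and Cyp2e1 stood at −2.30, −1.79, −2.52 and −0.60; the calls of Fga, Ahsg and Cyp2e1 ended without that library only, and that of Pck1 without 6 of the 20. Site-enriched genes numbered 6, with 36 by DESeq2, 97 by limma, 36 in the reduced and 21 in the strict set and 0 to 23 with 1 library left out; the calls of Slc14a2 and Cdh16 ended without 16 and 17 of the 20 libraries. With an animal block Cyp2e1, Pck1 and Ahsg stood at 4.66, 3.68 and 5.97 with no call, and by limma at 3.99, 1.94 and 4.15, with Fga at 3.45. In the strict set Cyp2e1 lost its call at 0.14 and Cdh16 at 7.92 above the nearest site (8.77 over all libraries).

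Under the label liver, genes of hepatocytes and of lung were both higher than at the other sites, with their highest levels in different libraries. The tests under this label average a library high in liver genes and a library high in lung genes, so they do not describe liver alone. Ahsg, a plasma protein of the liver, had 8854 TPM in T426 and 108.5 in the library labelled T3F, and the clotting factor F2 495.9 and 3.99. The club cell gene Scgb1a1 had 26790 TPM in the library labelled liver T3F and was listed at 0 in T426. All 16 hepatocyte genes (16 adjusted over the list alone), 24 of 24 complement and coagulation genes (24; camera adjusted p = 2.22e-24, adjusted p = 0.181 with an estimated correlation) and 10 of 11 alveolar genes (11) were higher. The alveolar genes numbered 0 of 10 in the reduced set, and without the library labelled liver T3F Sftpc, Sftpb and Scgb1a1 stood at −6.53, −2.40 and −5.91. Airway genes were higher in 4 of 9 (4 adjusted over the list alone) and in 1 of 10 in the reduced set, while Cyp2f2 had 555.5 TPM in the library labelled liver T3F and 285.5 in T426. The calls of Ass1, F2 and Serpind1 ended without T426, and those of Ass1, F2, Sftpc, Sftpb and Scgb1a1 by limma (4.27, 4.90, 6.06, 5.67 and 5.26). By edgeR 0 genes were site-enriched, with 3133 genes at an unadjusted p under 0.05 against the mean of the other sites, 16 enriched by DESeq2 and 1 by limma; there were 49 in the reduced set, led by Serpinf2, Apoa5 and Slc27a5, and 225 in the strict set, and in both of these 1 library stood for liver.

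In skeletal muscle, contractile genes were close between the animals and far above the mean of the other sites. The myosin light chain Mylpf reached 8361 ± 379 TPM (SD, n = 2) and lay 10.54 ± 0.57 log2 units above the mean of the other sites (adjusted p = 6.49e-08), and Myoz1, of the Z-disc, 11.29 ± 0.54 above. All 15 muscle fibre genes (15 adjusted over the list alone) and 26 of 27 sarcomere genes (26; camera adjusted p = 2.29e-49, adjusted p = 0.0078 with an estimated correlation) were higher. Oxidative phosphorylation genes were higher in 18 of 35 (29 adjusted over the list alone; adjusted p = 4.13e-16, adjusted p = 0.25 with an estimated correlation), such as Ndufb3 at 3.78 ± 0.58. Digestive enzyme genes of the pancreas were present in T3F: Prss2 had 2106 TPM there and 28.0 in T426, and Cela2a 786.2 and 9.96. Of 15 acinar genes 12 were higher (13 adjusted over the list alone), and 11 in the strict set; the calls of Prss2 and Cela2a ended without muscle T3F. Site-enriched genes numbered 43, with 255 by DESeq2, 140 by limma, 76 under an animal block, 248 in the reduced and 168 in the strict set and 0 to 205 with 1 library left out. The calls of Klhl31 (2298 ± 306.5 TPM), Tmem233 (1870 ± 107) and Mybph (495.2 ± 52.3) ended without 16, 6 and 12 of the 20 libraries, that of Klhl31 in the strict set (5.81 above the nearest site), that of Cela2a with an animal block (5.98) and those of Cela2a and Prss2 by limma (3.47 and 4.66).

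The sciatic nerve was marked by Schwann cell and matrix genes. Periaxin (Prx), of peripheral myelin, lay 8.02 ± 0.67 log2 units above the mean of the other sites (adjusted p = 4.34e-06), at 3983 ± 3225 TPM (SD, n = 2), and the transcription factor Sox10 6.92 ± 0.53 above. All 10 Schwann cell genes were higher (10 adjusted over the list alone) and 12 of 15 myelin genes (12; camera adjusted p = 8.82e-21, adjusted p = 0.0125 with an estimated correlation). Matrix genes were higher in 15 of 21 (20 adjusted over the list alone; adjusted p = 2.11e-16, adjusted p = 0.215 with an estimated correlation), including the proteoglycan Dcn at 4.29 ± 0.47. Sarcomere genes were higher in 13 of 27 (16 adjusted over the list alone; adjusted p = 2.71e-10, adjusted p = 0.181 with an estimated correlation). Acinar genes were higher in 12 of 15 (13 adjusted over the list alone), with Cela2a at 327.1 TPM in T3F and 4599 in T426; the number was 0 in the strict set, where Cela2a and Prss2 lost their calls at 6.26 and 6.10 (8.62 and 8.15 over all libraries), and these calls also ended without T426. Fat genes were higher in 4 of 12 (7 adjusted over the list alone), with Lep at 67.0 TPM in T3F and 0.588 in T426, and the calls of Lep and Plin1 ended without T3F. Site-enriched genes numbered 7, with 47 by DESeq2, 55 by limma, 44 in the reduced and 19 in the strict set and 0 to 24 with 1 library left out; the calls of Pmp2 (2405 ± 1050 TPM) and Sptbn5 (443.9 ± 32.9) ended without 17 and 17 of the 20 libraries. The call of Pmp2 also ended with an animal block (9.10 above the nearest site), by DESeq2 (8.43) and in the strict set (9.34), that of Lep by DESeq2 (6.12) and limma (2.92), and that of Plin1 by limma (2.55).

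In the ovary, follicle and steroid hormone genes were high in both animals. The inhibin subunit gene Inha had 4769 TPM in T173F and 7632 in T3F and lay 7.97 ± 0.57 log2 units above the mean of the other sites (adjusted p = 1.99e-05). Star, which moves cholesterol into mitochondria, had 745.6 and 13780 TPM, and Zp3, of the egg coat, 566.9 and 347.5. Of 14 granulosa, theca and luteal genes 13 were higher (14 adjusted over the list alone), of 9 oocyte genes 7 (8) and of 14 steroidogenesis genes 8 (10; camera adjusted p = 7.96e-13, adjusted p = 0.144 with an estimated correlation). By edgeR 0 genes were site-enriched, with 2254 genes at an unadjusted p under 0.05 against the mean of the other sites, 17 enriched by DESeq2, 79 by limma and 1 under an animal block. The number was 3 in the reduced set (Greb1, Amh and Fdxr), 6 in the strict set and 0 to 5 with 1 library left out.

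In the pancreas, enzyme and hormone genes stood high, at levels that differed widely between the animals. The elastase gene Cela2a had 23150 TPM in T3F and 58.83 in T173F and lay 15.76 ± 1.52 log2 units above the mean of the other sites (adjusted p = 8.3e-06), and glucagon (Gcg) 477.5 and 101.3 TPM. Insulin (Ins2) had 19770 TPM in T3F and was listed at 0 in T173F, as were Ppy and Iapp. The islet gene G6pc2 had 36.5 TPM in T3F and 84.2 in T173F. All 15 acinar genes (15 adjusted over the list alone), 9 of 11 islet genes (11) and 12 of 14 insulin secretion genes (13; camera adjusted p = 4.3e-09, adjusted p = 0.181 with an estimated correlation) were higher. Without T3F, Ins2, Ppy and Iapp stood at −3.58, −2.65 and −2.84. The site-enriched gene was Tdh (165.7 ± 26.8 TPM, SD, n = 2), a call that ended without 17 of the 20 libraries; 492 genes were enriched by DESeq2 and 7 by limma, 23 in the reduced and 13 in the strict set, each with 1 pancreas library, and 0 to 740 with 1 library left out, the highest without pancreas T3F. With an animal block the calls of Tdh (5.19 above the nearest site) and Ppy (12.38) ended, in the strict set that of Tdh (5.59), and by limma those of Ins2 (5.19) and Ppy (4.69).

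Cortex and medulla of the kidney, both from T3F, were compared as lone libraries. Proximal tubule genes had higher levels in cortex: the glucose transporter Slc5a2 had 271.6 TPM in cortex and 8.88 in medulla (log2 fold change 5.07 ± 1.38, SE), the lactate transporter Slc5a12 1043 and 27.3, and the anion transporter Slc22a8 446.7 and 9.34. All 12 proximal tubule genes had a positive difference with a median of 5.11, and 1 passed when adjusted over the list alone. The distal salt transporter Slc12a3 had 290.1 and 3.83 TPM, while the urea transporter Slc14a2 had 1.72 in cortex and 153.5 in medulla (−6.33 ± 2.08). Thick limb and distal genes were positive in 4 of 12 and gluconeogenesis genes in 10 of 12 (Slc37a4 83.6 and 18.5 TPM), with 0 passing in each when adjusted over the list alone. Over all 18323 genes edgeR called 0 in either direction, with 137 and 69 genes at an unadjusted p under 0.05, 51 and 35 called by DESeq2 and 12 and 7 by limma; 315 and 124 genes differed at least 8-fold in level. These tests compare the libraries, assumed to vary like the replicated sites. In simulated counts the edgeR test called 0 of 66 genes changed 64-fold here, so 0 calls by it are no sign of equal levels.

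Glandular and non-glandular stomach of T3F were compared in the same way. Here too the edgeR test called 0 of 66 simulated genes changed 64-fold, so 0 calls by it are no sign of equal levels. In the glandular part, intrinsic factor (Gif) had 1743 TPM against 15.8 (log2 fold change 7.63 ± 2.02, SE), the hormone ghrelin (Ghrl) 305.9 against 3.22 and the mucosal peptide Tff2 13960 against 88.8. In the non-glandular part the keratins of stratified epithelium led: Krt10 had 11530 TPM against 1.76 (−11.80 ± 3.05) and Krt1 37390 against 4.17, and Ivl, of the cornified envelope, had 745.7 TPM and was listed at 0 in the glandular part. All 12 gastric gland genes were positive with 3 passing when adjusted over the list alone, and 0 of 15 squamous genes were positive with 4 lower when adjusted over the list alone. Acinar genes were positive in 13 of 15 (Clps 73980 and 970.8 TPM) and smooth muscle genes in 1 of 10 (Myh11 114.9 and 826.2), with 0 passing in each. Over all genes edgeR called 0 in either direction, with 285 and 584 at an unadjusted p under 0.05, 194 and 427 called by DESeq2 and 31 and 170 by limma.

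Brown and inguinal fat of T3F were compared for heat-producing and storage genes. The edgeR test between them called 0 of 66 simulated genes changed 64-fold, so 0 calls by it are no sign of equal levels. The uncoupling protein Ucp1 had 3399 TPM in brown and 496.5 in inguinal fat (log2 fold change 3.55 ± 3.68, SE), the thyroid hormone deiodinase Dio2 122.8 and 13.9 (3.92 ± 1.80), and the carnitine transferase Cpt1b 449.3 and 69.7 (3.47 ± 1.25). Leptin (Lep) had 80.97 TPM in brown and 1699 in inguinal fat. Positive differences were found for 11 of 13 brown fat genes, 35 of 35 oxidative phosphorylation genes, 17 of 18 fatty acid oxidation genes and 6 of 12 adipocyte genes, with 0 passing in each list when adjusted over the list alone. Mitochondrial transcripts made up 37.03% of TPM in the brown fat library and 9.936% in the inguinal. By edgeR 0 genes were called in either direction, with 67 and 145 at an unadjusted p under 0.05; DESeq2 called 33 and 69, and limma 0 and 4.

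Right atrium came from T3F and right ventricle from T173F, so that chamber and animal cannot be told apart. As with the other lone libraries, edgeR called 0 of 66 simulated genes changed 64-fold, so 0 calls by it are no sign of equal levels. Sarcolipin (Sln), a regulator of the calcium pump, had 6203 TPM in atrium and 7.53 in ventricle (log2 fold change 9.95 ± 3.48, SE), the atrial light chain Myl4 5887 and 102.1 (6.15 ± 2.59), and Myl7 9172 with the ventricle listed at 0. The ventricular light chain Myl2 had 49.1 and 2559 TPM (−5.43 ± 1.74). Of 15 cardiomyocyte genes 6 were positive and 1 passed when adjusted over the list alone. Myot, a Z-disc gene, had 4.12 TPM in atrium and 96.65 in ventricle. By edgeR 0 genes were called in either direction, with 89 and 38 at an unadjusted p under 0.05; DESeq2 called 64 and 22, and limma 2 and 0.

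The cerebellum, a lone library of T3F assumed to vary like the replicated sites, was compared with the mean of the other brain sites. Of the 8 libraries of those sites 7 also came from T3F and 1, of hippocampus, from T426, so within the brain the difference between animals enters through hippocampus alone. In simulated counts 42 of 67 genes changed 16-fold were called there, with 15 false calls. Genes of granule and Purkinje cells led: the GABA receptor subunit Gabra6 had 683.4 TPM against 1.96 (log2 fold change 11.33 ± 1.25, SE, adjusted p = 0.0486), the granule cell gene Cbln3 2281 against 13.4 (7.86 ± 1.01, adjusted p = 0.00599), and the cadherin Fat2 257.4 against 0.961 (10.56 ± 1.28). Pcp2, of Purkinje cells, lay 7.25 ± 0.87 above and the calcium channel Itpr1 4.08 ± 0.55. By size alone, 153 genes were at least 8-fold higher in cerebellum and 217 at least 8-fold higher in the other brain sites. Of 13 cerebellum neuron genes 6 were higher (13 adjusted over the list alone). Of 12 projection neuron genes 3 were positive (Bcl11b −4.34 ± 2.08), of 10 oligodendrocyte genes 0 (Opalin −2.16) and of 9 astrocyte genes 6 (Slc1a3 1.78 ± 1.05), with 0 passing in each. In all, edgeR called 19 genes higher in cerebellum and 0 lower, with 398 and 107 at an unadjusted p under 0.05, 85 and 70 called by DESeq2 and 65 and 55 by limma. An animal block gave 29 genes, the reduced set 89 and 2, and the strict set 49 and 1. With 1 library left out the count was 9 without hippocampus T3F, hippocampus T426, nerve T3F or nerve T426, 10 without either library of duodenum or renal pelvis, 46 (and 1 lower) without pancreas T173F and 47 (and 1 lower) without pancreas T3F; the calls of Gabra6, Tgm6 and Serpinb2 ended without 13, 14 and 7 of 20 libraries. That of Gabra6 also ended with an animal block, with DESeq2 size factors (11.30 in each) and by DESeq2 (11.16). That of Tgm6 (10.23) ended by DESeq2 at 9.95 and in the strict set at 10.29, and that of Itpr1 by limma at 4.28.

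Small and large intestine were compared over 7 libraries, 4 of small and 3 of large. The main test treated these libraries as independent, though duodenum, jejunum, ileum and colon of T3F came from the same animal. Duodenum entered from both T3F and T426. The SE and p-values thus measure spread between segments of an animal as well as between animals. Among the genes named as higher in the small intestine, the glucose transporter Slc5a1 had 1025 TPM against 29.9 (log2 fold change 5.89 ± 0.43, SE, adjusted p = 0.00119), the peptide transporter Slc15a1 lay 5.16 ± 0.51 above (adjusted p = 0.00250), and the aminopeptidase Anpep 4.83 ± 0.65 (adjusted p = 0.00670). Each was above the 3 large intestine libraries in 4 of 4 small intestine libraries. Among those named for the large intestine, Hoxd10 fell by 10.94 ± 0.71 from large to small on the log2 scale (adjusted p = 0.000751), Hoxa11 had 50.65 TPM and was listed at 0 in the small intestine, and Mptx2, a secreted pentraxin, lay at −9.88 ± 1.80. The hormone gene Gast (gastrin) had 310.5 TPM and was listed at 0 in the large intestine. In total 1044 genes were higher in small and 1200 in large intestine by edgeR, and 478 and 4149 by limma. Cecum and rectum came from T173F and the small intestine from T3F and T426, so that colon T3F is the library of the large intestine that shares an animal with the small. An animal block therefore rests this contrast on colon T3F alone against duodenum, jejunum and ileum of T3F. Fewer calls under it need not mean smaller differences, and they do not tell animal from segment. With the animal as a block the counts were 2 and 2, and the 27 called genes named for this comparison lost their call, with Slc5a1 at 5.69, Anpep at 6.17 and Hoxd10 at −11.26. They were 640 and 532 without duodenum T3F, 674 and 719 without duodenum T426, 516 and 309 without jejunum, and 316 and 291 without rectum. In colon T3F itself Slc5a1 had 37.81 TPM against 722.9 to 1244 in the small intestine of the same animal, Anpep 25.55 against 743.3 to 1184, and Ceacam1 899.5 against 133.6 to 158.

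Gene groups of the intestine moved as follows. Enterocyte genes were higher in small intestine in 10 of 17 (12 adjusted over the list alone, with Cdx1, named after its value was seen, lower at −1.10 ± 0.37), gluconeogenesis genes in 8 of 11 (9) and oxidative phosphorylation genes in 6 of 35 (11), among them Sdhc at 1.28 ± 0.34 (adjusted p = 0.0401). Smooth muscle genes were higher in large intestine in 8 of 10 (8 adjusted over the list alone), led by Cnn1 at −2.74 ± 0.48 (adjusted p = 0.0125), and matrix genes in 18 of 21 (20). Macrophage genes were higher there in 4 of 11 (6 adjusted over the list alone), with the mannose receptor Mrc1 at −2.24 ± 0.30 (adjusted p = 0.00693), and B cell genes in 0 of 8 (4), with Ms4a1 at −5.93 (adjusted p = 0.0526). Of 12 colon epithelium genes 1 was higher in large intestine (1 adjusted over the list alone), the adhesion gene Ceacam1 at −1.95 ± 0.33 (adjusted p = 0.0122), while Car1 had 28560 TPM in cecum, 81.2 in colon and 66.6 in rectum. Among 11 goblet and Paneth genes 2 were higher in small and 1 in large intestine (3 and 1 adjusted over the list alone); Reg3g lay 7.01 ± 1.32 above, and Reg3b had 1804 TPM in duodenum T3F and was listed at 0 in T426. Of 19 clock genes 1 was higher and 2 lower in small intestine (1 and 2 adjusted over the list alone), with Per1 at −1.23 and Bhlhe41 at −2.64. Genes of other organs were present in the large intestine: the airway gene Scgb1a1 had 4017 TPM in colon and 4736 in rectum, with 14.41 in cecum, against 0.803 in the small intestine, 2 of 5 airway genes were higher there (2 adjusted over the list alone), and the acinar gene Sycn had 1734 TPM in colon T3F, 18.1 in rectum and was listed at 0 in cecum (0 of 11 acinar genes passed, 9 adjusted over the list alone). With the animal as a block these lists hold no more than the 2 and 2 genes called over all genes. Some differences were then smaller, with Cnn1 at −1.56, Sdhc at 0.97, Mrc1 at −1.95, Ceacam1 at −1.67 and Reg3g at 6.88. Others were larger, such as Scgb1a1 at −12.75 against −11.98 with no block, and Mptx2 at −11.25 against −9.88. Of the 27 called genes 13 kept their call without each of the 7 libraries in turn; 13 of the rest lost it without rectum, and Reg3b and Sdhc lost it by limma (4.63 and 0.39).

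**Figure D3:**
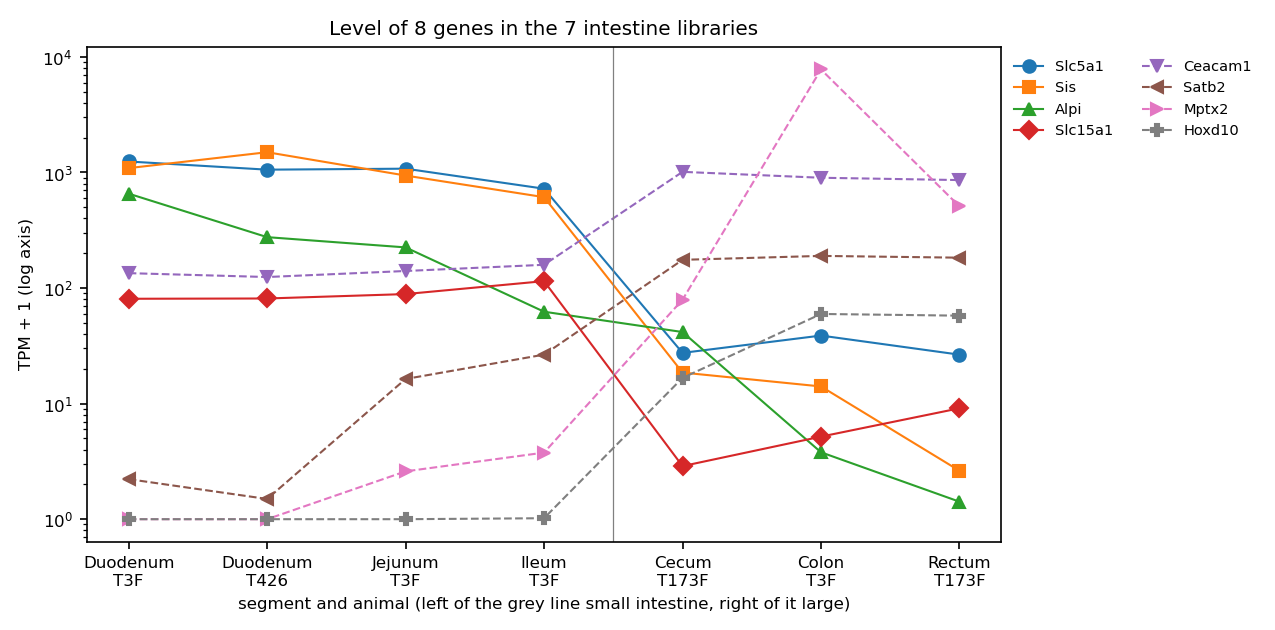
TPM + 1 on a log axis (vertical) of 8 genes in each of the 7 intestine libraries (horizontal), with a point for each library and a line joining the points of a gene. Slc5a1 lies between 722.9 and 1244 TPM in the 4 small intestine libraries and between 25.53 and 37.81 in the 3 large intestine libraries.

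Animals T426 and T3F were compared over the 7 sites that both supplied, with site as a block. Kdm5d, a gene of the Y chromosome in mouse, was higher in T426 by 9.65 ± 0.48 log2 units (SE, adjusted p = 5.28e-05), at 22.86 TPM against 0.0293. Of 9 listed sex-linked genes 4 were tested, and the other 3 of them were also higher in T426: Eif2s3y had 195.2 TPM in T426 and was listed at 0 in T3F, Ddx3y lay 3.73 ± 0.73 above and Uty 1.32 ± 0.23. Of these 4 genes 1 passed over all genes and 4 when adjusted over the list alone. Of 19 clock genes 0 passed over all genes and 4 were lower when adjusted over the list alone, with Nr1d1 at −1.65 ± 0.36 (17.9 and 61.3 TPM). Of 6 mitochondrial genes 0 passed and 5 were lower when adjusted over the list alone, with mt-Co2 at 1.12 TPM in T426 against 138.5 in T3F (adjusted p = 0.0958). All 32 ribosomal protein genes had a positive difference, with 0 passing (Rps20 0.92 ± 0.30), and 0 of 14 immediate early genes passed (Egr1 −2.48 ± 0.74). Of 3 germ cell genes tested 0 passed (Odf2 0.996 ± 0.689, and −0.19 without the pairs of liver, retina, hippocampus, femur and sciatic nerve). The filter on low counts left these 3 of 13 germ cell genes. It asks for counts in about as many libraries as an animal supplied, so genes high in a few T426 libraries were not tested. By edgeR 1 of 13643 genes was called higher in T426 and 0 in T3F, with 647 and 1791 at an unadjusted p under 0.05, 125 and 24 called with no filter, 263 and 236 by DESeq2 and 2 and 5 by limma. Without those 5 pairs the counts were 43 and 64. By size alone, over the 7 sites, 78 genes were at least 8-fold higher in T426 and 6 in T3F. Calls of mt-Co2 and mt-Co3 were gained with no filter (−6.73 and −5.10), by DESeq2 (−6.16 and −4.90), by limma (−5.84 and −4.80) and without the 5 pairs (−11.21 and −6.68). DESeq2 also called Uty, Ddx3y, Nr1d1, Rps20 and Egr1, and Ddx3y passed without the 5 pairs (5.04). Leaving out a pair gave 2 and 0 without duodenum, 2 and 3 without liver, 3 and 0 without muscle, and 1 and 1 without sciatic nerve, and dropping the site block gave 2 and 1. The animals also differed in depth, and T426 supplied no site deeper than 3827321 counts. Retina, hippocampus, femur and sciatic nerve of T426 also held testis transcripts. Of 172 genes found in testis and under 1 TPM in every T3F library, 96.51, 95.35, 88.37 and 50.58% were detected there. Whether these transcripts raised the sex-linked levels was not tested for these genes as a set. The comparison without the 5 pairs kept duodenum and muscle, where 2.326 and 1.163% of the 172 were detected in T426. Ddx3y lay 5.04 above there, against 3.73 over the 7 sites, so its difference did not need the libraries with testis transcripts. A difference in sex could not be told apart from one between these animals.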

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

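The tests of exchanged labels, of mixed RNA, of testis and pancreas RNA and of depth in this part were chosen only after the results were seen. Libraries were picked out by a wide gap to the rest of an organ's libraries in depth, detected genes, concentration of TPM or correlation, or by a list of marker genes whose mean log2(TPM + 1) passed 6 in a library of another organ. Over 20 groups tested for a gap, 5 were found, and chance gives about 1 in 20. Over 12 lists, 14 libraries were found.

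In animal T3F the library labelled lung had a mean of 11.21 for the hepatocyte list, against a median of 1.44 over all libraries, and the library labelled liver had 9.88 for the alveolar list, against 1.79. Lung RNA mixed into liver RNA is argued against, because the hepatocyte list in the library labelled liver lay −6.51 log2 units from liver T426 at the median and −4.79 at its highest member. An exchange of the labels stays a candidate explanation: the library labelled lung correlated with liver T426 at 0.913, the library labelled liver at 0.709, and the alveolar list was highest in the library labelled liver. Where such an exchange could have happened is not known, and the labels are kept here as given. No biological explanation was tested.

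In animal T426 the germ cell list reached 10.22 in retina, 9.17 in hippocampus and 6.76 in femur, against a median of 1.27. Expression of a few germ cell genes by these tissues is argued against: of 172 genes found in testis and under 1 TPM in every T3F library, a median of 91.86% was detected in retina, hippocampus, femur and sciatic nerve of T426, though 50.58% in nerve. A candidate explanation is testis RNA or reads in these libraries, since the levels of these genes followed testis T424 with a median rank correlation of 0.71 (0.518 in nerve), and they made up 21.09% of TPM in retina, 7.797% in hippocampus, 3.258% in femur, 0.3236% in nerve and 22.63% in testis itself. In other T426 libraries 1 to 11 of the 172 were detected. The share in retina lay near that in testis itself, yet retina genes remained at varied levels. In retina T426 against T3F, Csn3 had 1349 and 1435 TPM, Cplx4 655 and 2507, and Pde6h 302.4 and 2211. How a simple mix would give both was not tested. No other biological explanation was tested, and whether the RNA or the reads were mixed stays open.

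The acinar list reached 10.18 in sciatic nerve T426, 8.35 in muscle T3F, 8.28 in colon T3F and 7.14 in sciatic nerve T3F, against a median of 0.76. A low depth of the T3F libraries is argued against, since the lowest of their totals lay above those of 50.85% of all libraries. Nerve T426 had 2590940 counts, above 11.86% of libraries, and a low depth is argued against there because the 6 libraries with a lower total, pancreas left out, had at most 2.4 for this list. Pancreas RNA or reads in these libraries may account for it: over the acinar list the levels followed pancreas T3F with a median rank correlation of 0.976, at 20.15%, 3.968%, 3.163% and 1.4% of the pancreas level in the order above. No biological explanation was tested, and the correlation is over 15 genes listed as acinar.

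The remaining values are given without an explanation. The hepatocyte list reached 9.36 in renal pelvis T426 and 7.31 in cornea T3F. The gastric gland list reached 6.15 in duodenum T3F, against a median of 0.7. The Schwann cell list, whose members include genes that central myelin also expresses, reached 6.26 in medulla oblongata T3F and 6.88 in optic nerve T3F, against 3.46. Hippocampus T426 had 3006119 counts, the lowest total of 9 brain libraries (next 15509588), the most genes at 1 TPM (15687, next 14980) and the lowest median correlation with the other brain libraries (0.767, next 0.915). Brown fat T3F had 45.64% of TPM in its 10 most abundant genes (next 19.88% in the other fat libraries), and inguinal fat T3F had the highest median correlation with the other fat libraries (0.89, next 0.867).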

How the results depend on the processing

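In this part, the reduced set, the strict set, the comparison of animals without 5 pairs and the dispersion trend from all libraries were chosen only after the results were seen. Scaling by DESeq2 size factors kept every count of called genes within 1.5 times. Use of the left retina alone, run for the 10 sites and the lone libraries but not for the intestine or the animals, did so too, and dropping the filter did so in every comparison but that of animals; other thresholds kept the organ-enriched count within it (2410 to 2878), as did organs grouped by site name (2973). For named genes, 3113 of 3531 values with a library left out kept their side of the threshold, 397 lost the call, 7 gained it and 14 turned sign; in the other settings fixed beforehand 1083 of 1190 kept it, 74 lost it and 33 gained it, and in the added settings 349 of 379 kept it, 17 lost it, 3 gained it and 10 turned. The biological coefficient of variation was 0.802, 0.664 in the reduced set and 0.488 in the strict set; whether it sets the counts of calls was not tested. Depth was lowest in testis (678819 counts), pancreas T173F (1573234) and the T426 libraries (1691561 to 3827321). Each setting below changed the libraries, the test or its settings, a term of the model or the genes tested, and beyond that the cause was not tested. Between lone libraries of kidney, stomach, fat and heart, edgeR called 0 of 66 simulated genes changed 64-fold. A count that stays at 0 there is thus no sign of stability.

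By DESeq2 10947 genes differed among the 10 sites and by limma 12559, and 5667 to 12521 did with a library left out. Site-enriched genes are given in the order femur, hippocampus, retina, duodenum, renal pelvis, liver, muscle, nerve, ovary, pancreas. DESeq2 gave 126, 66, 116, 95, 36, 16, 255, 47, 17 and 492, and limma 63, 184, 197, 175, 97, 1, 140, 55, 79 and 7. The reduced set gave 103, 58, 123, 71, 36, 49, 248, 44, 3 and 23, and the strict set 39, 8, 48, 116, 21, 225, 168, 19, 6 and 13. Leaving out each library gave 0 to 75, 0 to 24, 0 to 84, 0 to 66, 0 to 23, 0 to 1, 0 to 205, 0 to 24, 0 to 5 and 0 to 740, and 18, 16, 16, 15, 18, 3, 18, 20, 3 and 20 of the 20 libraries moved the number over 1.5 times. Organ-enriched genes numbered 2758 to 3196. Of the list tests 6 passed with an estimated correlation, and 110 to 128 with a library left out.

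With the animal as a replicate block the site-enriched numbers were 13 in hippocampus, 20 in duodenum, 76 in muscle and 1 in ovary, the cerebellum had 29 genes, small and large intestine 2 and 2, and 18 of 220 list calls changed; of the named genes 39 lost their call, 27 of them in the intestine. It moved no other count over 1.5 times (6724 genes among the sites, 22 in femur, 56 in retina, 127 list calls) and changed the call of no other named gene. Between animals, dropping the replicate block of sites gave 2 and 1 genes and added a call of mt-Co3 (−5.36).

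Between lone libraries, DESeq2 gave 51 and 35 genes for kidney cortex and medulla, 194 and 427 for glandular and non-glandular stomach, 33 and 69 for brown and inguinal fat, 64 and 22 for atrium and ventricle, and 85 and 70 for cerebellum and other brain sites. Limma gave 12 and 7, 31 and 170, 0 and 4, 2 and 0, and 65 and 55. With a library left out, kidney, stomach, fat and heart stayed at 0, and the cerebellum had 9 to 47 genes and the other brain sites 0 to 1. The cerebellum had 89 and 2 in the reduced set and 49 and 1 in the strict set. Small and large intestine had 478 and 4149 genes by limma, and 316 to 1270 and 291 to 1599 with a library left out. Between T426 and T3F, no filter gave 125 and 24 genes, DESeq2 263 and 236, limma 2 and 5, and the set without 5 pairs 43 and 64; leaving out a pair gave 1 to 3 and 0 to 3.

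Some named genes turned sign in the reduced or strict set: in liver, Sftpc, Sftpb and Scgb1a1 stood at −6.67, −2.44 and −4.69 in the reduced set and at −6.92, −2.47 and −4.90 in the strict set, and in renal pelvis, Pck1, Fga and Ahsg stood at −0.61, −2.24 and −1.54 in the strict set. Between animals Odf2 stood at −0.19 without 5 pairs. Leaving out each library turned others, with these lowest and highest values. In liver, Sftpc ranged from −6.53 to 13.69, Sftpb from −2.40 to 15.78 and Scgb1a1 from −5.91 to 13.17, the lowest each without the library labelled liver T3F. In renal pelvis, Pck1 ranged from −2.52 to 6.98, Fga from −2.30 to 9.20, Ahsg from −1.79 to 9.28 and Cyp2e1 from −0.60 to 7.43, the lowest each without renal pelvis T426. Akap4 and Prm2 ranged from −4.36 to 11.33 and from −4.92 to 11.54 in hippocampus and Spata18 from −0.62 to 7.68 in retina, the lowest without T426 of that site. Ins2, Ppy and Iapp ranged from −3.58 to 17.01, −2.65 to 13.98 and −2.84 to 14.10, the lowest without pancreas T3F. Cel ranged from −6.675 to 0.0999 between small and large intestine, the highest without colon.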

Other observations

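The genes and lists in this part were chosen for print after their values were seen. The lists themselves were fixed before; no test was run on these values, and they come from lone libraries unless 2 animals are named. Adrenal gland is the site name of a library labelled kidney and of one labelled adipose, both from T173F. The steroid enzyme genes Cyp21a1 and Cyp11b1, of corticoid synthesis, had 22270 and 14920 TPM in the library labelled kidney and 4909 and 2949 in the one labelled adipose, and the steroidogenic list had means of 11.32 and 9.43 log2(TPM + 1), against 7.02 in ovary T3F and a median of 1.65 over all libraries. Chromaffin genes of the adrenal medulla stood at 8.1 and 5.25, with Pnmt, which makes adrenaline, at 455.0 and 83.5 TPM. The library labelled adipose also had 10.59 for the adipocyte list (median 3.0) and 7.24 for the lipid secretion list (median 3.07), so it holds genes of fat as well. In the eye, the corneal keratin Krt12 had 31650 TPM and Aldh3a1, an abundant corneal enzyme, 15470 TPM in cornea, and Rpe65, of the visual cycle, had 4102 TPM in the pigment epithelium against 73.55 in right retina T3F.

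Blood and immune lists were highest in the following libraries. The erythroid list stood at 9.3 in bone marrow, 8.42 in femur T3F, 7.95 in spleen and 7.09 in femur T426, against a median of 2.97. The B cell list stood at 7.53 in spleen, 5.81 in colon and 5.56 in the renal artery library, where the surface marker Ms4a1 had 176.8 TPM, against 834.2 in spleen. The cell cycle list stood at 7.37 in thymus, 6.47 in bone marrow and 5.96 in femur T3F (median 2.48). Squamous epithelium genes stood at 11.41 in non-glandular stomach, 10.73 in esophagus and 7.42 in rectum (median 0.9). The clock list was highest in the retina of T3F, at 5.76 and 5.73 on its sides, followed by 5.49 in cerebellum (median 4.28). Cartilage genes stood at 7.87 in trachea, with the proteoglycan Acan at 1406 TPM there and 182.8 in femur T3F.

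The splits of the libraries were the test of chance in the comparisons with 3 or more libraries per group. For small and large intestine, 1 of 35 splits, the real one, called as many genes: 2244 in total, and 30 in the highest of the others. The real split thus called far more genes than any other. A share of 1 of 35 is the smallest that these splits can give. Libraries of the same animal are also not exchangeable, so chance is not excluded. These splits ignore the animals: 2 of 3 large intestine libraries and 0 of 4 small came from T173F. An animal block, under which few genes were called, rests the contrast on colon T3F alone against the small intestine of T3F. For T426 and T3F, 2 of 64 exchanges of the animals within sites called at least as many genes, the real one with 1 and the highest other with 2. With 1 gene called, that share cannot tell the animals from chance, and another exchange, of duodenum, liver and muscle, called more than the real one.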
